A study of Macaca mulatta with 56 samples.

How the data were processed

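The samples were 56 libraries of messenger RNA from 14 old female rhesus macaques, each sampled in 4 brain regions: amygdala, hippocampus, occipital cortex and prefrontal cortex. All animals ate a Western-style diet and had their ovaries and uterus removed (OvH). In 7 animals implanted capsules released estradiol (hormone therapy, HT), and in the other 7 the capsules were empty. Groups were taken from the labels: 4 regions by 2 treatments gave 8 groups of 7 libraries, and the animal number joined the 4 libraries of an animal.

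The table of normalized read signal was made by the authors before it was deposited. Per the submitters' processing notes, reads were checked with FastQC 0.1.1.2, trimmed with Trimmomatic and aligned with STAR 2.7.3a to the build Mmul_10. Those notes also name edgeR 3.28.0 for normalization. The program that counted reads, its annotation release, its strand setting and the filter on low genes were not stated in the sources used here. The deposited table holds 17807 Ensembl identifiers by 56 libraries, and its file name calls the values upper-quartile normalized. The upper quartile was 2818.9375 in all 56 libraries. Whole reads could be recovered by undoing the scaling of each library (100% of values whole within 0.01 reads). Reads per library ranged from 34.63 to 93.34 mega-reads (median 59.88). The lowest mean over the 56 libraries was 17.96, and 6.83% of the values were 0. A gene symbol was paired with 15123 identifiers, and 2684 had none. There were 61 symbols on more than 1 identifier, covering 678 identifiers.

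The table has a defect that limits every statement made across regions. The amygdala libraries and the libraries of the other 3 regions do not hold the same transcript under each identifier. Across identifiers, the Spearman correlation of mean levels was 0.978 to 0.987 between the other 3 regions and 0.535 to 0.547 between the amygdala and each of them. These correlations are across genes, which are not independent replicates. Single libraries correlated at 0.959 to 0.995 with libraries on their own side and at 0.518 to 0.55 across. In the amygdala 0.576% of 695 small RNA identifiers had a mean above 1000, against 46.5% in hippocampus, 46.3% in occipital cortex and 47.5% in prefrontal cortex. MBP, the main myelin protein, had a mean of 608200 in amygdala and 0 in each of the other regions. The amygdala names were therefore taken as plausible and used for all identifiers. Outside the amygdala a name was used only where the level matched that in the amygdala. Identifiers were not reassigned.

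A level was called matching when the level of the other 3 regions was among the 20% nearest and within 4-fold. This rule was chosen after the data were seen, and the 4-fold limit was added after GAPDH and a U6 RNA had passed a first version without it. It held for 11298 identifiers (63.4%; 9896 with a symbol) and failed for 6509. By chance 18.6% would match, and hippocampus against the cortical regions gave 93.7%. From these shares about 59.7% of identifiers are aligned, and about 11.8% of the matching ones carry a wrong name.

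Within each region, HT was compared with OvH by limma 3.58.1 in R 4.3.3, with an intensity trend, on log2 of the value plus 1. Genes with a mean of at least 10 over the 14 libraries of the region were tested. The tests were two-sided, with the Benjamini-Hochberg adjustment and a threshold of 0.05. The average over regions used the mean log2 value of each animal. The difference of the HT effect between regions, and the differences between regions, were tested by limma with the animal as a block. The labels pair regions by animal. Deviations from group means were correlated over all genes with matching levels. Libraries of the same animal averaged 0.294 to 0.502 per pair of regions. Other animals of the group averaged below 0, which largely follows from subtracting the group means and is no separate evidence. Over the 500 matching genes that differed most between animals in the other regions, 54 of 56 libraries correlated best with their own animal. The exceptions were the hippocampus libraries of animals 30 and 43. These stayed joined to those animals in the average and in the tests between regions. Fitting all 56 libraries with the animal as a random block gave a consensus correlation of 0.184 and 1382 genes in amygdala. This fit used all identifiers, so its spread and correlation also came from those that hold different transcripts across regions. No replicate libraries were near copies of each other: the closest pair had a chi-square of 35.55 per degree of freedom.

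There were 24 pathway lists and 15 cell type marker lists, and 37 had at least 5 members to test. The mitochondrially encoded list had 0 members in the table and the red blood cell list 3, so neither was tested. Lists were tested by camera with a preset correlation of 0.01, by camera with an estimated correlation, by fry and by an exact permutation test of the list mean. Adjustment covered all lists and regions together. The list results given outside the amygdala were limited to members with matching levels, with 15 lists called. The count of 30 called lists covers all members in each region, 11 in amygdala and 19 elsewhere, where many names are wrong.

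Named genes followed a rule. Per comparison it took the 10 largest rises and 10 largest falls past the threshold. Where fewer than 5 passed it took the 5 smallest p in each direction, given as values. It added up to 4 members of each called list, the 5 genes highest in each region, and the receptors ESR1, ESR2, GPER1 and PGR. Outside the amygdala the rule was limited to matching levels, so ESR2 alone of the receptors is reported there. The lists, the tests, the rule for named genes and most alternatives were set before the data were examined. Exceptions are the match rule, the alternatives that use it, and those on 3 regions alone, on ribosomal proteins, on thinned reads, on 2 pairs of hippocampus libraries and on permuted list means. KIAA1755, ZSCAN26 and NRIP2 outside the comparisons where the rule took them, and the genes at the head of the other observations, were chosen after their values were seen. Some genes that the rule took are not reported here.

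Alternatives changed the pseudocount (0.25 or 5), the minimum mean (none or 50), the scaling (equal totals or median of ratios), the intensity trend, array weights, the animal block and a myelin marker covariate. Count tests on the recovered reads used edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0. Each animal was left out in turn.

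The scripts were tested on simulated data with 200 of 17807 genes changed. At a fold of 1.5 the amygdala test recovered 10.4% of changed genes, at 2-fold 62.7% and at 4-fold 100%. The same folds gave 10.4%, 46.3% and 92.4% in hippocampus, 10.4%, 64.2% and 97% in occipital cortex, and 35.8%, 85.1% and 98.5% in prefrontal cortex. For the average over regions recovery was 71.6%, 94% and 100%. For the difference of effects between regions it was 4.48%, 31.3% and 89.4%, and for the regions 49.3%, 91% and 100%. Simulated libraries of an animal shared no animal effect, unlike the real ones, so recovery for the average may be too high. Unchanged genes called numbered 4 in amygdala and 13 in prefrontal cortex. In the list test the 1 shifted list was called and 0 of the others. Simulated genes varied independently, while matching ribosomal proteins in amygdala had an estimated correlation of 0.79. The list test therefore does not show how often camera with the preset correlation calls real lists by chance.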

Results

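Messenger RNA was measured in amygdala, hippocampus, occipital cortex and prefrontal cortex of 14 ovariectomized female rhesus macaques aged 19.4 to 23.2 years. The animals ate a diet with 36% of calories from fat and 18.5% from sugars, against 13% and 6% in chow, and were operated on about 6 weeks after its start. Estradiol capsules gave 7 animals (HT) a mean serum estradiol of 82.1 pg/mL, and empty capsules left the other 7 (OvH) at 6.6 pg/mL. Brains were taken after a study of 30 months by one statement of the series text, which averages serum estradiol over 32 months, so the length of exposure is uncertain. Values are upper-quartile normalized read counts made by the authors, with SD and n = 7 per group. Mean read numbers per amygdala library, in mega-reads (M), were 65.15 ± 14.92 M in OvH and 53.1 ± 9.29 M in HT (exact permutation p = 0.0921). In hippocampus they were 59.66 ± 15.5 and 62.43 ± 14.31 M, in occipital cortex 65.13 ± 11.58 and 61.67 ± 8.275 M, and in prefrontal cortex 60.7 ± 12.07 and 59.32 ± 19.53 M.

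The amygdala columns of the table and those of the other 3 regions do not carry the same transcript under each identifier. The myelin gene MBP had a mean of 608200 in amygdala and 0 in hippocampus. The astrocyte gene GFAP had 172900 in amygdala and 0.179 in hippocampus, and the ribosomal gene RPL32 had 151700 and 0. Levels matched for 63.4% of identifiers, and for 27.3% and 27.7% when the other 3 regions were moved by 1 identifier in either direction. At a move of 50 identifiers 18.9% and 18.4% matched. Genes outside the amygdala are named below only where levels match, and about 11.8% of those names are estimated to be wrong.

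**Figure D1:**
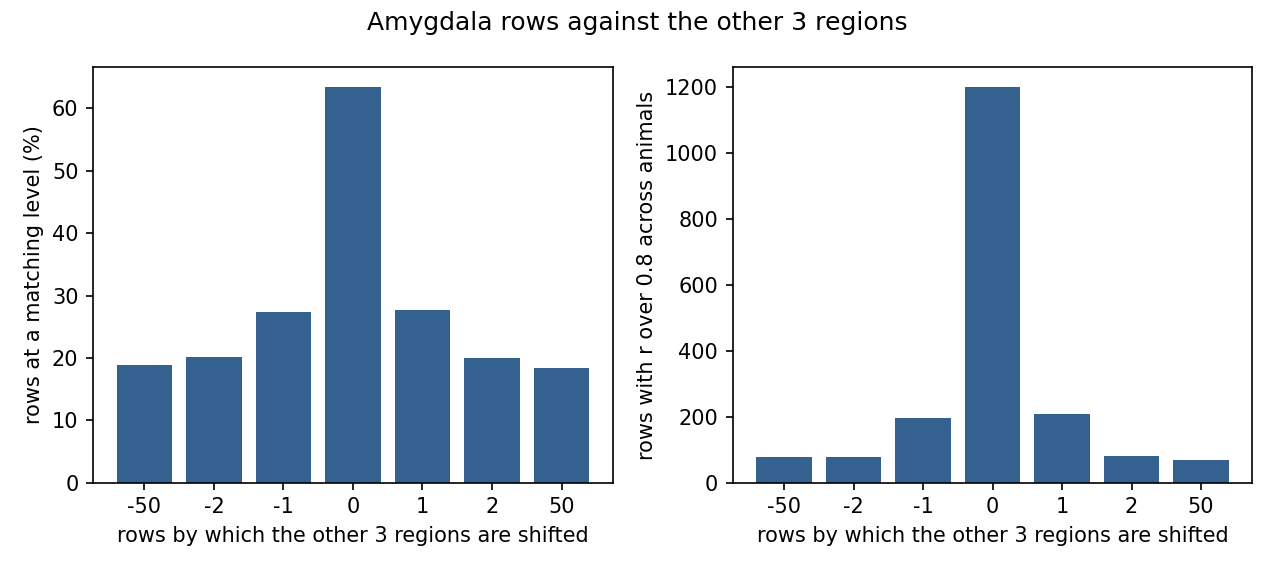
Amygdala table rows set against rows of the other 3 regions moved by the number of rows on the x axis; bars give the percentage of rows with matching levels, and the number of rows whose values vary together across the 14 animals (r above 0.8). Matching fell from 63.4% at 0 to 27.3% and 27.7% at 1 row, still above the 18.9% and 18.4% at 50 rows.

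The first question was what long estradiol treatment changed in the amygdala. Transcripts of ribosomal proteins, the protein part of the ribosome, were about 2-fold more abundant in HT animals: 39 of 44 tested rose and 0 fell (44 adjusted over the list alone), with a mean log2 difference of 1.16. RPS27A (ENSMMUG00000015563), a fusion of ubiquitin and a ribosomal protein, reached 378900 ± 171000 against 101300 ± 31900 in OvH (log2 1.81, adjusted p = 0.00674, above every OvH animal in 6 of 7). Of 52 nuclear-encoded respiratory chain subunits 22 rose and 0 fell (30 rose and 1 fell adjusted over the list alone), with a mean of 0.53. With myelin markers as a covariate 12 of them rose (mean 0.48), and with equal totals 19 did (mean 0.32). Among them NDUFB9 of complex I averaged 104000 ± 42200 against 30670 ± 8980, and COX7B of cytochrome c oxidase 141400 ± 63300 against 42460 ± 17500. The list of 19 oligodendrocyte and myelin markers had a mean of 0.43 (camera adjusted p = 0.0437, but 0.895 with an estimated correlation). Of its members 3 rose and 0 fell, over all genes and adjusted over the list alone, with MBP at 811900 ± 203000 against 404500 ± 226000, MOBP rising by log2 1.46 and the gap junction gene GJB1 by 1.14.

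Lists of synaptic, glycolytic and neuronal transcripts lay lower in HT amygdala by camera with a preset correlation. With an estimated correlation none of the 37 lists was called there, and adjusted p was 0.769 to 0.895 for the 11 lists given here, the 3 higher ones included. Of 27 presynaptic vesicle release genes 3 fell and 0 rose (mean -0.36; 4 fell adjusted over the list alone). Among them were the vesicle protein gene SYP, 30930 ± 8200 against 50980 ± 14900 (log2 -0.71), and SV2B (-0.57). Of 25 glycolysis genes 1 fell (mean -0.25; 1 adjusted over the list alone), the neuronal glucose transporter gene SLC2A3 (-0.53), while HK1 stood at -0.41 and did not pass. Of 17 pan-neuronal markers 1 fell (mean -0.26; 1 adjusted over the list alone), the endocytosis gene DNM1 (-0.66). Of 30 interferon response genes 2 fell (mean -0.16; 1 rose and 3 fell adjusted over the list alone), the antiviral genes MX1 (-0.70) and IFI44L (-0.94), while IFIT1 stood at +0.71 with adjusted p = 0.0619. Of 29 immediate early genes 1 fell (mean -0.32; 0 adjusted over the list alone), the transcription factor gene JUNB, 205.8 ± 83.1 against 544.8 ± 358 (log2 -1.31, adjusted p = 0.0496). Of 22 circadian clock genes 1 fell (mean -0.18; 1 adjusted over the list alone), the clock kinase gene CSNK1D (-0.43). Of 37 glutamatergic synapse genes 1 rose (mean -0.20; 1 adjusted over the list alone), the scaffold gene HOMER2 (+0.49), against the direction of the list, and GRIN1 stood at -0.58 without passing. None of 35 monoamine and acetylcholine genes passed (mean -0.30; 0 adjusted over the list alone), with the muscarinic receptor gene CHRM1 at -0.76 and adjusted p = 0.0704.

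Single genes with the largest rises in HT amygdala were IL3RA, a subunit of the interleukin 3 receptor, at 108.4 ± 99.3 against 6.97 ± 1.83 (log2 2.82, adjusted p = 0.0329), and GTSF1, a factor of the germ line small RNA pathway, at 291.6 ± 158 against 44.9 ± 32.2 (6.5-fold, adjusted p = 0.0142). SNORA70 (2.29), PGPEP1L (1.74), RNU6ATAC (1.69), RPL26 (1.75) and RPS29 (1.69) followed. Falls were smaller: the lysosomal transporter gene SLC7A14 went from 1744 ± 318 to 983.9 ± 225 (log2 -0.83, adjusted p = 0.00895), and PGM2L1 from 4863 ± 1170 to 2658 ± 732 (-0.87). C1QTNF1 (-0.98), PNMA6F (-0.88), ATP8A2 (-0.87), PRKAR1B (-0.76) and HOOK1 (-0.76) also fell. Transcripts of the hormone receptors did not pass: ESR1 differed by 0.09 (adjusted p = 0.914), ESR2 by -0.01 (0.993), PGR by 0.18 (0.833) and GPER1 by -0.49 (0.298). With myelin markers as a covariate the calls of IL3RA (adjusted p = 0.0745), GTSF1 (0.0608), JUNB (0.185), IFI44L (0.103), MX1 (0.109), DNM1 (0.0642), SV2B (0.0562), SLC2A3 (0.0536), CSNK1D (0.0989), HOMER2 (0.0864), GJB1 (0.0654) and MBP (0.109) ended, as did those of PGPEP1L, RNU6ATAC, C1QTNF1, PNMA6F, ATP8A2, PRKAR1B and HOOK1. With the animal as a block in a fit of all regions those of SLC7A14 (0.0859), IFI44L (0.108), SV2B (0.101), CSNK1D (0.0612), C1QTNF1 (0.0575), ATP8A2 (0.093) and HOOK1 (0.132) ended, and HOMER2 did not pass with equal totals (0.15). IL3RA did not pass without animal 31, 33, 34, 35, 37, 38, 41, 42 or 43 (adjusted p from 0.0505 to 0.0739), nor JUNB without 30, 33, 34, 35, 36, 37, 38, 40, 41, 42 or 43 (0.0519 to 0.106). The fit with the animal block takes the spread of a gene from all regions. It is therefore a weak check where a name may cover another transcript elsewhere, as for C1QTNF1, whose level did not match. The signs of ESR1, ESR2 and PGR turned under other settings. GJB1 and MBP belong to the myelin markers whose mean is the covariate, so the loss of their calls with it is partly built in. The symbols SNORA70, RPS27A and MOBP stand on more than 1 identifier.

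In amygdala 994 of 16129 genes were higher and 118 lower in HT by limma, 1112 in all, and 3474 had an unadjusted p under 0.05. With the animal as a block in a fit of all regions 1382 passed, but its spread also came from identifiers without matching levels. Camera adjusted p was 8e-31 for ribosomal proteins (adjusted p = 0.769 with an estimated correlation), 2.81e-08 for the respiratory chain (adjusted p = 0.883 with an estimated correlation), 1.83e-04 for presynaptic genes (adjusted p = 0.769 with an estimated correlation) and 3.22e-04 for glycolysis (adjusted p = 0.769 with an estimated correlation). For myelin markers and interferon genes it was 0.0437 and 0.046 (adjusted p = 0.895 with an estimated correlation for both), and for glutamatergic and pan-neuronal genes 0.00982 and 0.0178 (adjusted p = 0.887 with an estimated correlation for both). For monoamine, immediate early and clock genes it was 0.00563, 0.00701 and 0.033 (adjusted p = 0.769 with an estimated correlation for the 3). Camera calls ended with the myelin covariate for glutamatergic (adjusted p = 0.165), immediate early (0.0528) and clock genes (0.216), and with equal totals for monoamine (0.0525) and interferon genes (0.108). Over members with matching levels alone, which are fewer, the calls of myelin markers (adjusted p = 0.125), interferon (0.0673), immediate early (0.105) and clock genes (0.0951) ended. The exact permutation test of the list mean gave p = 0.00233 for ribosomal proteins, with the mean of 7 of 7 HT animals above the OvH median, and p = 0.00758 for the respiratory chain (6 of 7), each adjusted to 0.323 over all lists and regions.

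The direction of the split depended on the scaling: 89.4% of the genes that passed were higher, but 37.9% with libraries scaled to equal totals (618 higher, 1013 lower; median shift of all genes -0.201) and 66.3% by edgeR (675 higher, 343 lower; median shift -0.103), while ribosomal proteins stayed higher and presynaptic genes lower with equal totals (0.95 and -0.57). Normalized totals were 71.12 ± 4.464 M in HT and 61.36 ± 4.081 M in OvH (exact permutation p = 0.00291). The count became 588 with myelin markers as a covariate, 3525 with array weights, 1732 by DESeq2 and 0 with the ribosomal mean as a covariate, and leaving out single animals gave 2362 without 32, 548 without 33, 639 without 35, 603 without 36, 718 without 37, 724 without 38, 736 without 42 and 622 without 43. The count of 118 lower genes moved further. It was 14 without 33, 36 without 34, 29 without 35, 25 without 36, 49 without 37, 38 without 38, 60 without 40, 31 without 42 and 27 without 43, but 218 without 31, 733 without 32 and 225 without 39. It was 62 with the myelin covariate, 64 without the intensity trend, 279 with the animal block, 439 by DESeq2 and 1248 with array weights.

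**Figure D2:**
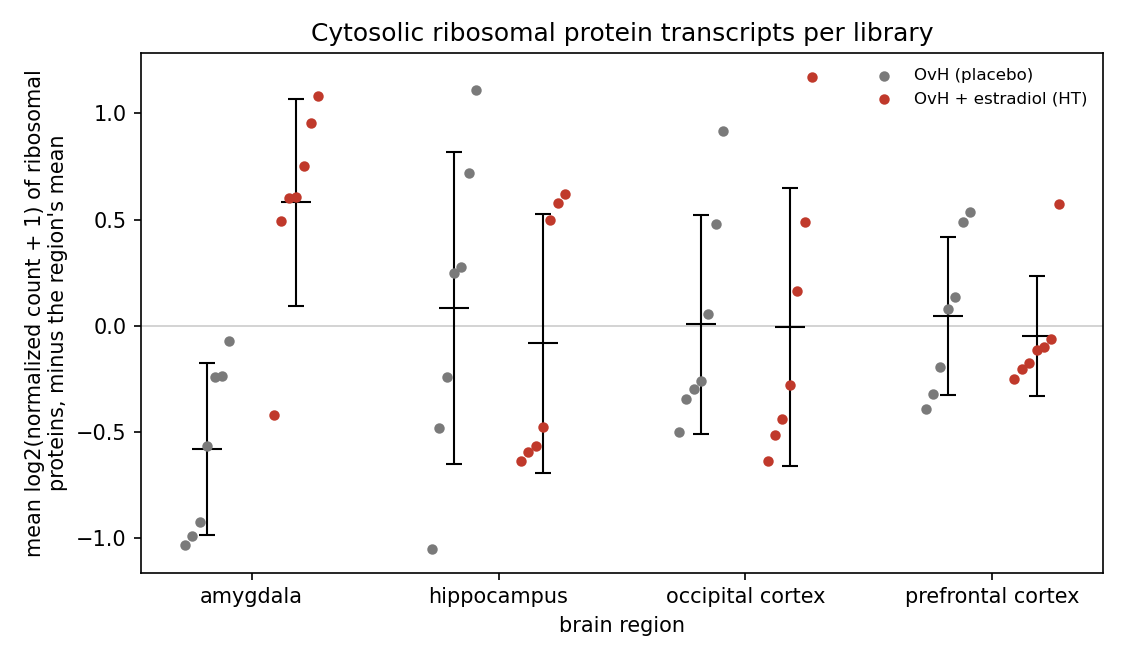
Mean log2(normalized count + 1) of cytosolic ribosomal protein genes in each library, less the mean of its region. OvH and HT animals are shown in the 4 regions. Points are libraries, horizontal marks the group means and capped bars the SD around them. In amygdala 6 of 7 HT animals lie above every OvH animal, and HT animal 39 lies at -0.42.

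In hippocampus the gene with the smallest p was KIAA1755 (ENSMMUG00000020172), at 1688 ± 379 in HT and 754.6 ± 171 in OvH (log2 1.17, adjusted p = 0.187), with 7 of 7 HT animals above every OvH animal. EYA1, a transcriptional cofactor gene, showed the same separation (log2 0.78, adjusted p = 1). Genes picked for their small p tend to separate in this way, here and below, so the separation adds no support. PRRX1 (1.03), EDARADD (0.88) and PI16 (1.21) leaned higher, and ANKRD37 (-0.90), NMRK2 (-1.54), DYNC1I2 (-0.48), the ERK phosphatase gene DUSP6 (-0.75) and LRRC20 (-0.31) lower, none past the threshold. The estrogen receptor gene ESR2 differed by -0.14, a sign that turned in other settings. By camera the list of 13 myelin markers lay higher in HT (12 members higher, 1 lower, mean 0.42, adjusted p = 8.78e-06, but adjusted p = 0.899 with an estimated correlation), with UGT8, an enzyme gene of myelin lipid synthesis, at 5232 ± 1280 against 3428 ± 1010 (log2 difference 0.63). Also higher were the lists of 25 extracellular matrix genes (24 higher, 1 lower, mean 0.44, adjusted p = 1.29e-05, but adjusted p = 0.899 with an estimated correlation), such as COL6A3 (0.89) and VCAN (0.51), and of 20 cholesterol genes (18 higher, 2 lower, mean 0.24, adjusted p = 9.02e-04, but adjusted p = 0.899 with an estimated correlation), such as HMGCS1 (0.48).

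Oligodendrocyte precursor markers in hippocampus had a mean of 0.35 over 7 genes (adjusted p = 0.0399) and meningeal markers one of 0.64 over 6 (adjusted p = 0.042), each with adjusted p = 0.899 with an estimated correlation; OLIG2 stood at 0.38 and LUM at 0.99. Lower in HT hippocampus was the list of 39 respiratory chain genes (38 lower, 1 higher, mean -0.17, adjusted p = 8.78e-06, but adjusted p = 0.899 with an estimated correlation), such as UQCRB at -0.25. The 36 ribosomal protein genes had a mean of -0.16 (adjusted p = 0.00424, but adjusted p = 0.902 with an estimated correlation), with RPL9 at -0.22, and a mean of 0.01 without animal 43. No member of these 7 lists passed, over all genes or adjusted over the list alone. Over all genes limma passed 0 of 16317, with 335 at an unadjusted p under 0.05. These 335 were 2.05% of the genes, fewer than chance alone gives on average. By edgeR 0 passed, by DESeq2 12 and by limma with equal totals 1, which was KIAA1755 (adjusted p = 0.0419). Hippocampus libraries of animals 30 and 43 correlated better with another animal than with their own. Those of 33 and 40 had raised choroid plexus markers. Without either pair limma passed 0 genes. The number at an unadjusted p under 0.05 was 849 of 16247 without 30 and 43, and 273 of 16309 without 33 and 40. The first number is near what chance alone gives on average, and the second is below it.

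In occipital cortex genes that leaned higher in HT were the cyclin gene CCNL2 (log2 0.86), CPA4 (1.03), KIAA1755 (729.6 ± 192 against 430.3 ± 189, log2 0.83), PAQR8 (0.33) and ANKRD34B (0.52). Leaning lower were SNTG2 (201.7 ± 70.2 against 374.6 ± 128, -0.90), LNX2 (-0.78), SFN (-1.07), the nuclear receptor interacting gene NRIP2 (-0.70) and MYH13 (-1.12), while ESR2 differed by 0.04, a sign that turned without single animals. These genes each had adjusted p = 0.999. Endothelial markers lay higher by camera (13 genes, 11 of them higher, mean 0.23, adjusted p = 0.00148, but adjusted p = 0.899 with an estimated correlation), among them the angiopoietin receptor gene TEK (0.40) and ERG (0.33). Meningeal markers (6 genes, mean 0.47, adjusted p = 0.0154, but adjusted p = 0.899 with an estimated correlation) included LUM (0.96). GABAergic genes (20, of which 13 higher, mean 0.12, adjusted p = 0.0294, but adjusted p = 0.899 with an estimated correlation) included the scaffold gene GPHN (0.17). No list member passed, over all genes or adjusted over the list alone. Limma passed 0 of 16138 genes, with 303 at an unadjusted p under 0.05. These 303 were 1.88% of the genes, fewer than chance alone gives on average. By edgeR and DESeq2 0 passed, by the fit with the animal block 1, and leaving out animal 42 gave 1.

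In prefrontal cortex ZSCAN26, a zinc finger gene, stood at 3469 ± 432 in HT and 2474 ± 354 in OvH (log2 0.49, adjusted p = 0.766), with 7 of 7 HT animals above every OvH animal. UGP2 (0.44) and NCBP1 (0.39) leaned higher. NRIP2 (-0.51), LNX2 (-0.72), the kinase gene MAP2K3 (-0.39), MARCHF10 (-0.68) and ZNF575 (-0.33) leaned lower, and ESR2 differed by -0.40, none past the threshold. Pan-neuronal markers lay higher by camera (14 genes, mean 0.14, adjusted p = 0.00728, but adjusted p = 0.899 with an estimated correlation), with STMN2 at 0.27 and INA at 0.28. Heat shock genes (21, of which 16 higher, mean 0.10, adjusted p = 0.00799, but adjusted p = 0.902 with an estimated correlation) included the chaperone genes HSPH1 (0.41) and HSPA4 (0.29). Meningeal markers (6, of which 5 higher, mean 0.50, adjusted p = 0.0108, but adjusted p = 0.899 with an estimated correlation) included LUM (1.22) and COL3A1 (0.74). Endothelial markers (13, of which 11 higher, mean 0.17, adjusted p = 0.0449, but adjusted p = 0.902 with an estimated correlation) included EMCN (0.42). The list of 36 ribosomal protein genes lay lower (29 lower, 7 higher, mean -0.09, adjusted p = 0.0193, but adjusted p = 0.902 with an estimated correlation), with RPL13 at -0.23. Of these members 0 passed over all genes, and 1, LUM, rose adjusted over the list alone. Limma passed 0 of 16286 genes, with 603 at an unadjusted p under 0.05. These 603 were 3.7% of the genes, fewer than chance alone gives on average. By edgeR 0 passed and by DESeq2 6, MAP2K3 (adjusted p = 0.0264) among them, and leaving out animal 42 or 43 gave 1.

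Averaged over the 4 regions, KIAA1755 had a log2 difference of 0.95 (adjusted p = 0.429) with HT animals higher in each region. Its means were 958.6 ± 253.7 against 503.8 ± 285 in amygdala (adjusted p = 0.0345) and 1063.8 ± 263 against 643.5 ± 246.8 in prefrontal cortex (adjusted p = 1), both picked after their values were seen. The average of KIAA1755 passed with array weights (adjusted p = 0.0433), by edgeR (0.0469), by DESeq2 (1.55e-05) and without animal 32 (0.0345), while its call in amygdala ended with equal totals (0.0686), by edgeR (0.0807) and without most single animals. NRIP2 averaged -0.59 (adjusted p = 0.429), with 7 of 7 HT animals below every OvH animal, and its difference was negative in amygdala (-0.73, adjusted p = 0.0184), hippocampus (-0.42), occipital cortex (-0.70) and prefrontal cortex (-0.51). By DESeq2 the average of NRIP2 passed (adjusted p = 6.13e-04). The averages join the hippocampus libraries of animals 30 and 43 to those animals, which these libraries did not match best. They were not rerun without both animals. ZSCAN26 (0.44), EYA1 (0.63), the receptor phosphatase gene PTPRZ1 (0.29) and CYP4F11 (0.65) leaned higher and TPGS1 (-0.70), LNX2 (-0.46), SPINDOC (-0.26) and UBALD2 (-0.39) lower, and ESR2 differed by -0.13. By limma 0 of 17807 identifiers passed, some of which average different transcripts, with 1166 at an unadjusted p under 0.05, and 0 of 11298 with matching levels (590); edgeR passed 10 and DESeq2 293, and leaving out animal 32 or 42 gave 1.

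**Figure D3:**
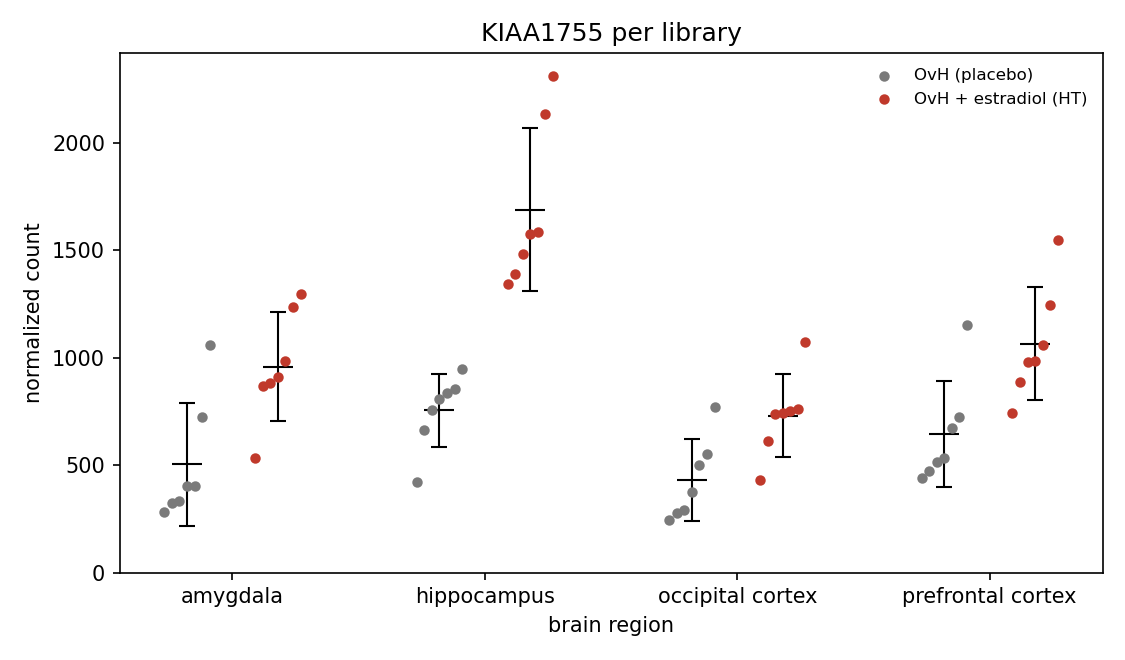
KIAA1755 normalized counts in each library of OvH and HT animals in the 4 regions. Points are libraries, horizontal marks the group means and capped bars the SD around them. In hippocampus the 7 HT animals lie above all 7 OvH animals, with means of 1688 and 754.6.

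The next question was whether the effect of estradiol differed between regions. Among genes with matching levels 1 of 11298 passed, which has no symbol (adjusted p = 0.0286; 1141 at an unadjusted p under 0.05). The named genes with the smallest p did not pass the test over the 4 regions. The synaptic scaffold gene SNTG2 differed by 0.44 in amygdala, -0.42 in hippocampus, -0.90 in occipital cortex and -0.05 in prefrontal cortex (adjusted p = 0.232). Of the 6 pairs of regions, its effect in occipital cortex less that in amygdala passed (-1.34, adjusted p = 0.0471), as 1 of 2 genes in that pair, with 0 genes in each of the other pairs. RPL37 differed by 1.53, -0.35, 0.01 and -0.13, and NMRK2 by 0.74, -1.54, 0.38 and 0.40, each with adjusted p = 0.232. For ribosomal proteins the log2 difference in amygdala exceeded the mean of the other regions by 1.22 (exact permutation p = 0.00699, adjusted to 0.518 over the lists and regions). Over all identifiers 90 passed, of which 7 had matching levels, so most compare different transcripts. Without the animal block 93 passed. The count of 90 became 0 of 16354 with the amygdala left out (181 at an unadjusted p under 0.05), and 143 without animal 31, 161 without 32, 49 without 33, 50 without 35, 52 without 36, 359 without 39, 58 without 42 and 59 without 43.

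Regions differed in most genes with matching levels. Folds are against the mean log2 level of the other 3 regions together, not against the next highest region. FIBCD1 was 16.6-fold higher in hippocampus, with a mean of 8805 against 1371 in amygdala, 99.6 in occipital and 447.2 in prefrontal cortex. TTR, the thyroid hormone carrier made by choroid plexus, was 16-fold higher there, at 206100 ± 504000, an SD larger than the mean. ADGRG2 (15.1-fold), TSPAN18 (13.7) and the lipoxygenase gene ALOX15 (13.5) were also highest in hippocampus. Occipital cortex had the most of the receptor tyrosine kinase gene MET (2844, 7.31-fold), the Wnt agonist gene RSPO2 (4.38-fold), the orphan receptor gene ESRRG (3.79), VAV3 (3.76) and COL26A1 (3.67). Prefrontal cortex had the most of OVOL2 (1014, 5.52-fold), the adrenergic receptor gene ADRA1B (a log2 difference of 1.71), PDIA2 (3.26-fold) and the glucose-responsive transcription factor gene MLXIPL (2.99). FSTL4 was 3.51-fold higher there by this measure, but its mean of 1504 ± 379 was within the spread of the 1419 ± 352 in occipital cortex. In amygdala TMSB10 (3.73-fold), MMD (3.72), PCBD1 (3.71), ITM2B (3.6) and CRYM (3.42) were highest, but the match rule admits no difference there far beyond 4-fold. Limma with the animal as a block passed 10328 of 11298 genes with matching levels (91.4%). It passed 16842 of 17807 identifiers in all, and 11320 of 16354 identifiers over the 3 regions without amygdala. Without the block 16203 of all identifiers passed.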

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

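Tests chosen only after the result was seen were those of depth, of scaling, of displaced identifiers, of expression differences between regions, of exchanged or wrong labels and of the respiratory chain mean, and the splits for hippocampus, occipital cortex, prefrontal cortex, the average, and lists in amygdala and in the other 3 regions; the alternatives on matching levels, ribosomal proteins and thinned reads also came later.

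In HT amygdala 39 of 44 ribosomal protein genes and 22 of 52 respiratory chain genes were higher. With reads thinned to the smallest library 1078 of all genes passed, against 1112. Thinning keeps the share of each transcript and could hardly move transcripts this abundant, so it does not decide on depth as a cause. For ribosomal proteins the values argue against scaling as the whole cause (mean 0.95 and 36 genes with equal totals). They also argue against a myelin share as the whole cause (35 genes and a mean of 1.20 with the marker covariate). For the mean of the respiratory chain, 0.53 (standard error 0.152), they argue against either as the whole cause, at 0.32 (0.106) with equal totals and 0.48 (0.171) with the covariate. Each may account for a part, since 22 genes passed but 19 with equal totals and 12 with the covariate, where the standard error was larger. Scaling may account for part of the split of all genes, since the share that was higher went from 89.4% to 37.9% with equal totals. An axis on which libraries differ without treatment cannot be told apart from the effect: across genes, which are not independent, the HT difference correlated at 0.39 with slopes on the ribosomal mean within groups of prefrontal cortex, short of the 0.5 set in advance, and at 0.588 in hippocampus and 0.565 in occipital cortex, which were not set in advance. An effect of estradiol, an RNA quality or dissection difference, or both may underlie it; no measure of RNA quality was used here, so the biological reading stays open and untested.

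Identifiers carry unlike levels in amygdala and the other 3 regions. When moved by 1 place 27.3% of identifiers matched, against 18.9% and 18.4% at 50 places. No such move was made among the other 3 regions, so likeness of neighbouring identifiers could also give an excess at 1 place. Other values argue against real differences of expression as the whole account. Of 695 small RNA identifiers 0.576% had a mean above 1000 in amygdala, against 46.5% in hippocampus. MBP had a mean of 608200 in amygdala and 0 in hippocampus. Displacement by neighbouring places is a candidate explanation: 195 identifiers varied together across animals at a move of 1, against 77 and 67 at a move of 50. The step at which it arose was not tested.

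Hippocampus libraries of animals 30 and 43 correlated with the other regions of their own animal at 0.0499 and 0.061, and best with those of animals 43 (0.271) and 37 (0.191). The library of 43 correlated best with animal 37, which argues against an exchange of the 2 labels as the whole account. The best correlation with any other animal was 0.271, while the other 54 libraries correlated with their own animal at 0.398 to 0.931. The lowest of these was occipital cortex of animal 30, whose comparison included the doubtful hippocampus library. For a library of usual quality this argues against a label from another of the 14 animals. A library of poor quality could correlate weakly with every animal, its own included, so neither label account is excluded. A library from an animal outside the study or a mixed sample may remain. No biological explanation was tested.

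The treatment groups were compared with other splits of the animals, in 100 of the 1716 possible splits, the real one included. In amygdala 1 split, the real one, gave as many genes (1112, highest other 2), so chance is unlikely to give this count. Splits that were not drawn were not examined. In the difference between regions 2 splits, the real one included, gave as many as 90 identifiers (highest other 144). Of the other splits 51 gave at least 1, so chance is unlikely to give this count but is not excluded. Most of the 90 compare different transcripts, and no split was run on matching levels alone. For the region differences the region labels were instead exchanged within each animal, 100 times with the real labels included. Of these, 1 gave as many as 16842 identifiers (highest other 5208). Identifiers that hold different transcripts in amygdala would by themselves favour the real labels. The exchange was not run on matching levels, so it does not decide whether expression differed. For the 30 lists called over all members 41 splits gave as many (highest other 46). For the 11 lists called in amygdala 24 splits did (highest other 17), and for the 15 called elsewhere with matching levels 61 did (highest other 36), so chance is not excluded for any of these list counts. Counts of 0 cannot be tested this way, since any split gives as many (100 of 100); the highest others were 143 in hippocampus, 190 in occipital cortex, 0 in prefrontal cortex and 1 for the average. The 1 split with 143 genes set 4 HT and 3 OvH animals against the rest and the 1 with 190 genes set 5 and 2, with 2 and 3 genes in the next highest, so they may reflect a structure of the samples other than treatment, which was not identified.

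The difference between regions passed its test for 90 identifiers in all and for 1 with matching levels. In 308 groups of 7 libraries, 22 held a library far from the others, by the gap to the nearest over the whole range; chance gives about 1 in 20, or 15.4. In amygdala OvH animal 32 stood apart for ATP8A2 (0.593; 927.3, nearest 1843) and MAOB (0.796; 19380, nearest 14470). It also stood apart for the means of glutamatergic (0.703; -0.59, nearest 0.08), presynaptic (0.606; -0.56, nearest 0.08) and clock genes (0.609; -0.49, nearest 0.03). HT animal 39 stood apart for the mean of ribosomal proteins (0.606; -0.42, nearest 0.49). HT animal 41 did so for HK1 (0.612; 16470, nearest 12560) and GJB1 (0.609; 7361, nearest 5225), HT animal 42 for PGR (0.664; 52.4, nearest 24.7) and HT animal 37 for ZSCAN26 (0.636; 8191, nearest 5698).

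In hippocampus OvH animal 43 stood apart for NMRK2 (0.785; 93.5, nearest 29.0) and RPL9 (0.595; 84330, nearest 52640), HT animal 41 for ESR2 (0.607; 47.5, nearest 21.5) and HT animal 40 for OLIG2 (0.676; 4343, nearest 3159). In occipital cortex HT animal 37 stood apart for ANKRD34B (0.713; 384.7, nearest 673.4), SFN (0.577; 25.1, nearest 14) and ERG (0.692; 664.4, nearest 462.5), and HT animal 40 for LUM (0.818; 1337, nearest 371.3). In prefrontal cortex OvH animal 32 stood apart for LNX2 (0.641; 1412, nearest 891.9) and KIAA1755 (0.601; 1151, nearest 723.8). HT animal 40 stood apart there for RPL13 (0.773; 41920, nearest 26710) and for the mean of ribosomal proteins (0.773; 0.57, nearest -0.06).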

How the results depend on the processing

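Alternatives added after the data were seen were matching levels alone, 3 regions alone, the ribosomal covariate, thinned reads, pairs of hippocampus libraries left out and permuted list means. In amygdala the count of 1112 was 1109 and 1116 with pseudocounts of 0.25 and 5, 1088 with no minimum, 1130 with a minimum mean of 50, 957 by median of ratios, 967 without the trend, 1018 by edgeR, 1382 with the replicate block, 1631 with equal totals and 1078 with thinned reads. It was 588 with myelin markers as a covariate, 3525 with array weights, 1732 by DESeq2, 524 with matching levels (fewer genes tested) and 0 with the ribosomal mean as a covariate (454 at an unadjusted p under 0.05), where the covariate itself differs between the groups; the cause of the first 3 was not tested. Leaving out 1 animal gave 548 (without 33) to 2362 (without 32), with counts within 1.5 times of 1112 being 1078 without 30, 1255 without 31, 791 without 34, 1576 without 39, 801 without 40 and 975 without 41.

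Counts of 0 moved as follows, for causes not tested. Hippocampus gave 1 with equal totals and 12 by DESeq2, and 0 without each animal. Occipital cortex gave 1 with the replicate block and 0 to 1 without single animals. Prefrontal cortex gave 6 by DESeq2 and 0 to 1 without single animals. With array weights limma passed 0 in each of these regions, but more genes had an unadjusted p under 0.05. They numbered 860 against 335 in hippocampus, 1857 against 303 in occipital cortex and 1215 against 603 in prefrontal cortex. The average gave 1 with array weights, 10 by edgeR, 293 by DESeq2 and 0 to 1 without single animals. The 90 identifiers that differed between regions were 72 and 123 with the pseudocounts, 134 with equal totals, 93 by median of ratios, 108 without the trend and 49 to 359 without single animals (33 and 39), but 1 with matching levels and 0 over 3 regions, where fewer were tested. Region differences were 10328 with matching levels (fewer tested). The 30 called lists were 26 with equal totals, 24 with the myelin covariate, 22 with matching levels and 18 to 32 without single animals (35 and 31; 19 without 41), but 0 by camera with an estimated correlation, 0 by fry and 0 by the permutation test.

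Signs turned mostly for genes that had not passed, for causes not tested. ESR2 in amygdala (-0.01) went to 0.067 with pseudocount 5, 0.15 with the myelin covariate, 0.49 by edgeR and 0.56 by DESeq2, and ranged from -0.34 to 0.40 without single animals, above 0 without 31, 32, 35, 36, 38, 39 and 40. ESR1 there (0.09) went to -0.12 with equal totals, -0.078 by edgeR and -0.91 with the ribosomal covariate, and ranged from -0.065 to 0.25, below 0 without 33, 34, 36, 38 and 43. PGR (0.18) went to -0.023 with equal totals and ranged from -0.059 (without 42) to 0.31. ESR2 in hippocampus (-0.14) went to 0.14 by edgeR and 0.13 by DESeq2 and ranged from -0.41 to 0.10, above 0 without 36 and 39. In occipital cortex ESR2 (0.04) ranged from -0.18 to 0.27, below 0 without 31, 34, 37, 38 and 43. Averaged, ESR2 (-0.13) went to 0.0093 with the myelin covariate, 0.077 by edgeR and 0.082 by DESeq2 and ranged from -0.32 to 0.049, above 0 without 39 and 40. With the ribosomal covariate, COX7B and GSTM3, which had passed, turned to -0.087 and -0.16, and GRIA2 to 0.024, MAOA to 0.14, HLF to 0.064 and SYT1 to 0.34. TF in hippocampus turned to -0.011 with the myelin covariate, and the ribosomal list there ranged from -0.34 to 0.011 (without 43). TF is itself one of the myelin markers, so its change is partly built into that covariate.

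For the named amygdala genes 918 other values kept direction and side of the threshold, 108 lost the call, 51 gained one and 14 turned; without single animals these were 826, 174, 23 and 13. For genes named elsewhere they were 1333, 0, 11 and 6, and 1376, 0, 1 and 9. The call of IL3RA ended with the myelin covariate (adjusted p = 0.0745), that of JUNB without a minimum (0.0555) and with the myelin covariate (0.185), that of HOMER2 with equal totals (0.15) and that of MBP with the myelin covariate (0.109). MBP is itself one of the myelin markers, so its lost call is partly built into that covariate. Depth did not limit the count in amygdala by much, at 1078 with reads thinned to the smallest library against 1112. Simulated 1.5-fold changes were recovered for 10.4% of changed genes there, and whether depth, spread or the number of animals limits this was not tested.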

Other observations

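The genes in this part were picked after their values were seen, as members that passed in amygdala from lists that were not called. In HT amygdala 3 neuropeptide genes of the GABAergic and interneuron list were higher, while 23 of its 32 members lay lower and 9 higher (mean -0.11, camera adjusted p = 0.101). CCK averaged 13730 ± 1616 against 7306 ± 1926 (log2 0.95, adjusted p = 0.00674), TAC1 3825 ± 1107 against 2095 ± 621.5 (0.88, adjusted p = 0.0192) and VIP 1563 ± 250.7 against 946.8 ± 362.4 (0.80, adjusted p = 0.0333), each with 7 of 7 HT animals above the OvH median. These 3 were the members of the list that passed (4 adjusted over the list alone). The calls of CCK and TAC1 held with equal totals and by edgeR, while that of VIP ended with equal totals (0.0721) and by edgeR (0.0928), and TAC1 missed without animal 36 (0.0502).

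Of 17 microglia markers 3 rose and 0 fell in HT amygdala, both over all genes and adjusted over the list alone, while the list was not called (mean 0.24, camera adjusted p = 0.121). Over the 12 members with matching levels the mean was 0.06, with 6 higher, 6 lower and 0 past the threshold. AIF1, an actin-binding protein gene of microglia, averaged 2413 ± 540.1 against 1177 ± 375.4 (log2 1.06, adjusted p = 0.0069), and the protease gene CTSS 1456 ± 275.4 against 889.7 ± 134.7 (0.70, adjusted p = 0.00899). GPR34 stood at 0.68 (adjusted p = 0.031, but 0.147 with equal totals). Of 32 oxidative stress genes 5 rose (10 adjusted over the list alone; mean 0.17, camera adjusted p = 0.187), among them PRDX4 (0.74) and GSTM3 (0.93). Of 18 astrocyte markers 2 rose, S100B (1.05, adjusted p = 0.0146) and FABP7 (1.13, adjusted p = 0.0333), with a list mean of 0.00. Over the 13 astrocyte markers with matching levels 6 lay higher and 7 lower, with a mean of 0.07. With the animal block the calls of AIF1 (0.112), GPR34 (0.117), VIP (0.0555) and PRDX4 (0.0561) ended. That fit takes its spread from all regions, where a name may cover another transcript, so it is a weak check of these calls.

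Lists built on estrogen action did not pass in amygdala: 25 receptor and steroid genes had a mean of -0.05 (camera adjusted p = 0.442) and 28 estrogen-induced genes of reproductive tissue one of -0.01 (0.606), with 0 members past the threshold in either, also adjusted over the list alone. Other lists without a call had means of -0.10 (28 heat shock genes, 1 rose), -0.13 (35 insulin and lipid genes, 2 rose), -0.06 (37 Alzheimer disease risk genes, 1 fell), -0.09 (36 autophagy and lysosome genes, 4 rose and 1 fell), -0.06 (27 cholesterol genes, 1 rose), -0.05 (33 growth factor genes, 0), 0.17 (27 complement and antigen presentation genes, 1 rose), 0.00 (30 cytokine genes, 1 rose), 0.07 (38 extracellular matrix genes, 0) and 0.08 (37 DNA methylation and histone genes, 0). Marker lists without a call were hippocampal neurons (-0.23), endothelium (-0.18), oligodendrocyte precursors (-0.07; 1 rose), cortical layers (-0.04; 1 rose), meninges (0.35), pericytes (-0.07; 1 rose), amygdala and basal forebrain (0.09; 1 rose), choroid plexus (-0.08), perivascular macrophages and lymphocytes (0.18) and medium spiny neurons (-0.01; 1 rose). The meningeal mean of HT animal 42 in amygdala was 2.89 above the region's mean.

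Averaged over regions, with matching members, extracellular matrix genes had a mean of 0.22 (exact permutation p = 0.0117, adjusted to 0.431 over 37 lists) and meningeal markers one of 0.52 (exact permutation p = 0.0309, adjusted to 0.571). Means of choroid plexus and ependymal markers in hippocampus were 3.43 above the region's mean in OvH animal 33 and 3.76 in HT animal 40.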
